A study of Mus musculus with 8 samples.

How the data were processed

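Brains of mice that were fasted for 17 h or fed were measured on 8 single-colour Agilent expression arrays, 4 per group, per the labels. Groups and replicate numbers came from the sample titles. Cy3-labelled cRNA had been prepared from 0.1 ug of total RNA, per the labels' protocols. The deposited scanner files give each spot's brightness as an intensity. Per the file headers these were made with Feature Extraction 11.0.1.1, with spatial and multiplicative detrending switched on. The headers give the background method only as code 7. The submitters' processing notes name Agilent Feature Extraction 10.10.1.1. Both versions are given as found. The array design refers to mm9, per the file headers. The deposited series table holds a linear ratio per spot. Set against the scanner values, it equals the signal over each array's 75th percentile divided by a factor that is constant per probe, with a spread over arrays of 0.000179 on the log2 scale. Its scale and direction follow from this, and the baseline behind the factor stays unknown. Column medians of that table were 0.970, 0.993, 0.973 and 0.987 for fasted replicates 1 to 4 and 0.987, 1.02, 0.991 and 1.02 for fed replicates 1 to 4. It was used only as an alternative.

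Processed signals were taken to log2 and each array's 75th percentile over non-control spots was subtracted. The 75th percentile was 1651 to 1944 in intensity units. Control spots and spots with an outlier flag (128 to 217 per array) were left out, and spots of a probe were averaged, 399 probes having 10 spots. A probe counted as well above background on an array where at least 0.5 of its spots did, and probes were kept when this held on at least 4 of the 8 arrays, whatever the group. This kept 26066 of 39429 probes. Replicate spots of a probe varied by a median of 3.19% to 4.95% per array. Accessions of 27427 probes matched the RefSeq gene table of assembly GRCm38.p6, which was used for names only; other probes kept the name in the files. Coordinates are those of the array design in mm9, and the exon or untranslated region under a probe was not analysed here.

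Fasted and fed arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, fasted minus fed), with Benjamini-Hochberg adjustment over the kept probes and a threshold of 0.05. A gene took the values of its kept probe with the highest mean signal, which does not use the groups, and kept that probe under the alternatives wherever it was present. Of 2797 genes that passed, 854 had more than 1 kept probe and 36 of these had another probe past the threshold in the opposite direction. Where a gene was not well above background on any array of a group, only a lower bound of the fold is given. It sets the mean of the brighter group against the mean, over the dimmer group's arrays, of the higher of the probe's own signal and the lowest signal well above background. Lists of pathway, cell type and region genes were written before the data were examined and tested with camera at a preset correlation of 0.01 where at least 3 members were measured, with adjustment over 36 lists. Camera with an estimated correlation and fry were run beside it.

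Genes named in the text were chosen by a rule fixed before the data were examined. It takes the 12 largest rises and 12 largest falls among genes that passed with fully separate groups, up to 4 members of each list with the smallest p, and a fixed set of genes known from feeding, stress, activity and clock biology. Of the fixed set, Hspa1b and Eif2s3y were not among the kept genes. Btg2 and Itm2a were named outside the rule. A gene that the rule takes is not reported here.

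Arrays lay on 2 slides, each with 2 arrays of each group, and slide was tested as a batch: 110 genes passed for a difference between slides. The test had no block, since no label pairs the mice, and replicate numbers were then checked for pairing. Deviations of the same-numbered fasted and fed arrays from their group means correlated at 0.18 to 0.29, above 0.1 in every pair. The replicate block is therefore given as an alternative. Same-numbered arrays share a slide and sit side by side, at positions 1 and 2 or 3 and 4. Pairing of the samples cannot be told apart from slide and neighbouring position. Fed replicate 1 correlated best with fasted replicate 2, at 0.27. Arrays with different numbers correlated at 0.05 to 0.27 on the same slide and at -0.39 to -0.10 across slides, and 7 of 8 arrays correlated best with the array of their own number.

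The procedure was tested on simulated data for the fasted against fed comparison, over 26066 probes with 200 changed in each of 5 runs. It recovered 30.1% of probes changed 1.2-fold, 79.7% of those changed 1.5-fold and 91.5% of those changed 2-fold. Over the 5 runs 42 unchanged probes passed, and 0 lists passed. The simulated probes vary independently, so this says nothing on lists of correlated genes or on slides. In the real comparison far more probes passed, 4417, than the 200 changed per simulated run. The adjusted threshold was therefore stricter in the simulation, and the recovered shares do not carry over to the real comparison.

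Alternatives tried were quantile normalization, median scaling, normexp background correction with an offset of 50, the deposited series table, no filter and a filter on all 8 arrays, a trend and robust variance model, array weights, the replicate block, slide as a block, each array left out, outlier spots kept, an adjusted p under 0.1, a fold of at least 1.5, the mean of a gene's probes, and the other list tests. Slide with linear array position, an olfactory bulb marker score as a covariate, and each slide alone were added after the data had been seen.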

Results

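Brain gene expression was measured in mice that had been fasted for 17 h and in fed mice, with 4 arrays per group and 8 arrays in all. Each array carried 39429 non-control probes for mouse transcripts, read in a single Cy3 colour. Between 24567 and 27220 probes were well above background on an array, which is 62.3% to 69.0% of them, and 26066 probes entered the test. No spot was saturated. The labels do not say how many mice gave each sample, so the p-values measure the spread between these samples, which may be partly technical. The number of arrays limits the precision of every value below. Arrays of a group correlated with the others of that group at a mean r of 0.995 to 0.997 across probes, and no arrays held identical values.

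The comparison asks how gene expression in the brain differs after food deprivation. Fasted brain had higher levels of Agrp, the appetite-stimulating peptide of arcuate neurons, by 3.05-fold (95% confidence interval 2.47 to 3.78, n = 4 per group), and of Plin4, a lipid droplet protein, by 7.93-fold (4.91 to 12.8). Of 32 glucocorticoid-responsive genes 14 rose, and of 33 PPAR-alpha targets and genes of fatty acid oxidation 12 rose. Of 25 genes of cholesterol biosynthesis 16 fell, as did 10 of 17 heat shock genes, 10 of 18 chaperones of the endoplasmic reticulum and 11 of 25 activity-regulated immediate early genes.

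Most differences were small. Of 14912 genes tested with limma, 2797 (18.8%) passed the threshold, with 1426 higher and 1371 lower in fasted brain. With median scaling 1270 genes were higher and 905 lower. The 2797 genes had a median absolute difference of 1.18-fold, and 152 of them differed by at least 1.5-fold, 83 higher and 69 lower. Differences of at least 2-fold were seen for 15 genes that rose and 4 that fell. At the level of probes, 4417 of 26066 passed, 2189 higher and 2228 lower. The 4 fasted values lay entirely to one side of the 4 fed values for 2744 of the genes that passed, and for 27.4% of all genes tested, where chance gives 2.86%. The median log2 difference of all kept probes was -0.01. With slide as a block 3120 genes passed, and with the replicate number as a block 2416. Within slide 1 alone and within slide 2 alone, with 2 arrays per group, limma called 0 genes, while 3475 and 2320 genes had an unadjusted p under 0.05. Without fasted replicate 1 the count was 1764 genes, and without fasted replicate 2 it was 1843. Fasted arrays sat at positions 1 and 3 of a slide and fed arrays at positions 2 and 4, so alternating position cannot be told apart from fasting.

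Among genes well above background in both groups, the largest rise was in Plin4 (NM_020568), which encodes the lipid droplet protein perilipin 4. Its log2 difference was 2.99 ± 0.30 (SE, n = 4 per group; limma adjusted p = 0.00154). The probe lies on chromosome 17 at 56240055 to 56240114 of mm9, the build of the array design. Sult1a1, a sulfotransferase, rose 3.10-fold (log2 1.63 ± 0.17, SE; adjusted p = 0.00161), and its other kept probe gave a log2 difference of 1.61. Agrp (NM_007427) rose by a log2 difference of 1.61 ± 0.13 (SE; adjusted p = 0.000967). Its probe lies on chromosome 8 at 108090600 to 108090659 of mm9. Scaled log2 signal of Agrp was -1.54 ± 0.09 in fasted and -3.15 ± 0.29 in fed brain (SD, n = 4 each). Angptl4, an inhibitor of lipoprotein lipase, was 2.30-fold higher (adjusted p = 0.00641), and its value in fasted replicate 3, 1.42, stood apart from a mean of 0.68 in the other fasted arrays. Mfsd2a, a transporter of lysophosphatidylcholine carrying docosahexaenoic acid, rose 2.30-fold (adjusted p = 0.000967). Gli1, a transcription factor of hedgehog signalling, rose 2.27-fold, Xdh, xanthine dehydrogenase, 2.29-fold, and Pla2g3, a secreted phospholipase, 2.30-fold, with 0.83 and 0.23 (log2) on other probes of Pla2g3, the last with an adjusted p of 0.633. Itgad, Scn10a and Lao1 were well above background on the 4 fasted arrays and on 0 of the fed arrays. Taking the lowest signal well above background as a floor for the fed arrays, their levels were at least 2.36-fold, 2.01-fold and 2.20-fold higher in fasted brain, with adjusted p of 0.0019, 0.00144 and 0.006.

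**Figure D1:**
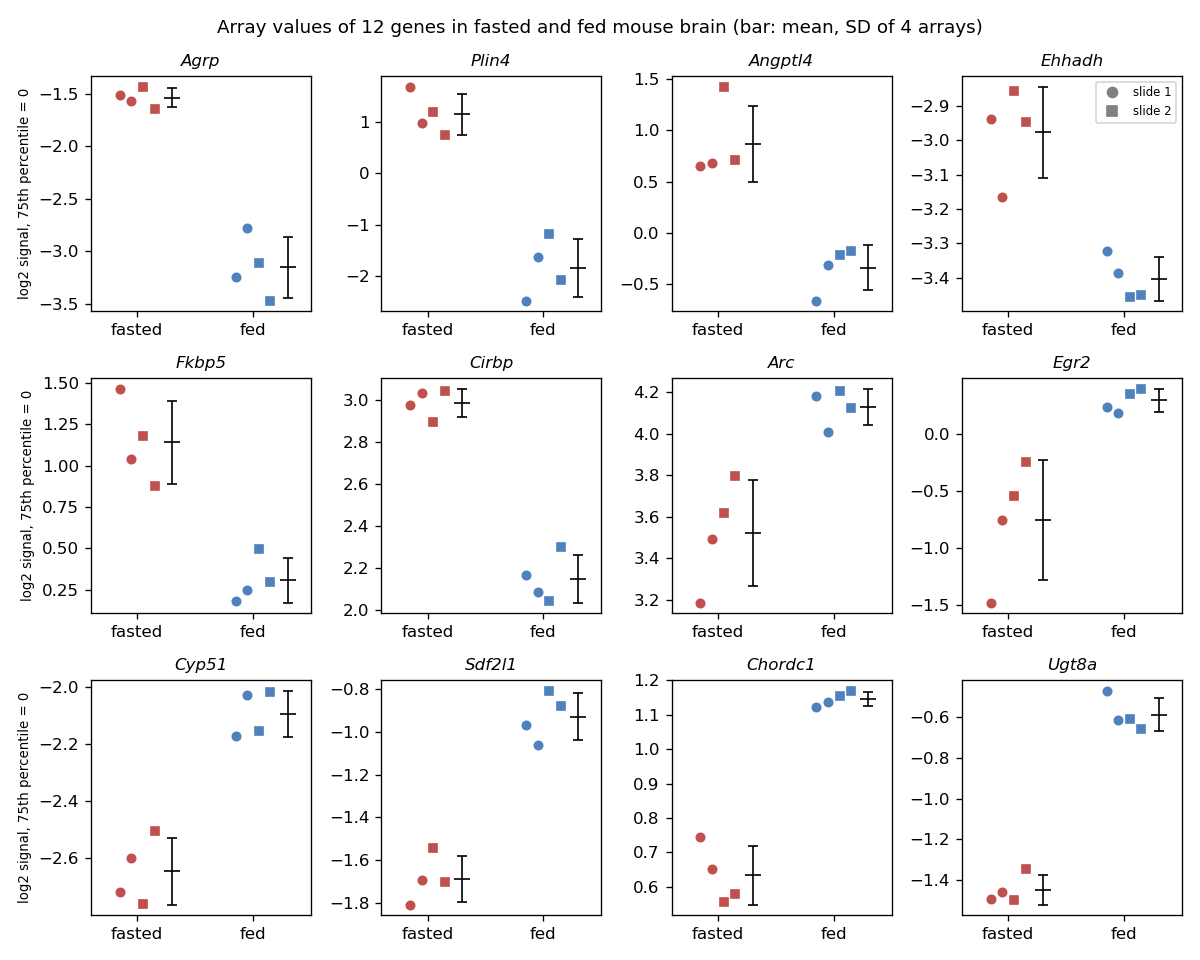
Scaled log2 signal (75th percentile of the array = 0) of 12 genes on each of the 4 fasted and 4 fed arrays. Circles are arrays of slide 1, squares arrays of slide 2, and bars give the mean and SD of 4 arrays. Agrp averaged -1.54 in fasted and -3.15 in fed brain, and the groups did not overlap for any of the 12 genes. For Agrp, Plin4, Angptl4, Egr2 and Ugt8a the naming rule itself required separate groups.

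Among genes that fell, Tnfrsf25 (NM_033042), a receptor of the tumour necrosis factor family, changed most. It was 2.32-fold lower in fasted brain (95% confidence interval 1.96 to 2.75; limma adjusted p = 0.00109), with its probe on chromosome 4 at 151494160 to 151494219 of mm9. Rpe65, the retinoid isomerohydrolase, was 2.16-fold lower (adjusted p = 0.00218) and Noxred1 2.07-fold lower (adjusted p = 0.000635). Egr2, an activity-regulated transcription factor, was 2.08-fold lower (95% confidence interval 1.43 to 3.02). Gkn3 was 1.98-fold lower, Bfsp2 1.92-fold, and Apln, which encodes the peptide apelin, 1.80-fold. Ugt8a, the enzyme that makes the myelin lipid galactosylceramide, was 1.82-fold lower (95% confidence interval 1.67 to 1.98; adjusted p = 0.000635). Tmprss5 was 1.78-fold lower, Baz1a 1.77-fold and Atf3 1.76-fold. Atf3 did not pass with the replicate block (adjusted p = 0.0786; 0.012 to 0.311 over its alternatives). Rhox1 also fell (adjusted p = 0.00697) and was well above background on 1 of the fasted arrays and 4 of the fed arrays, so no fold is given for it.

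Of 23 measured feeding-related hypothalamic peptides and receptors, 1 rose (Agrp), 1 fell (Bdnf, by 0.30 on the log2 scale) and 21 did not pass. Adjusted over the list alone, 1 rose and 0 fell. Npy, the peptide co-expressed with Agrp, differed by 0.11 ± 0.04 (log2, SE; adjusted p = 0.0972), and Pomc, the precursor of the satiety peptide alpha-MSH, by -0.26 ± 0.08 (adjusted p = 0.0531). With slide as a block Pomc passed (adjusted p = 0.0298; 0.0269 to 0.394 over its alternatives), and with the replicate block it did not (adjusted p = 0.0592). Hcrt and Pmch gave log2 differences of 0.08 and 0.06, with adjusted p of 0.407 and 0.484. The list as a whole had a median of 0.06 (camera adjusted p = 0.397).

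Gene lists fixed before the data were examined were tested against all other genes with camera. Of 36 lists, 8 passed with the preset correlation, 3 higher and 5 lower. With an estimated correlation 0 passed in limma's camera, and 2 lists had an unadjusted p under 0.05. The rotation test fry called 14, with 7 of these 8 among them but not oxidative phosphorylation (adjusted p = 0.0615). Of the 35 splits of the 8 arrays into 4 and 4, the real split included, 9 gave at least 8 lists. Other groupings of the same arrays thus reached as many calls with the preset correlation. Most of these others exchanged a single fasted array for a fed one, so they still held part of the fasting contrast. The split of fasted 1, fasted 4, fed 1 and fed 4 from the rest, with 2 arrays of each group, gave 8. The counts of member genes rest on the gene-level test.

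Glucocorticoid-responsive genes were higher in fasted brain. Of 32 measured members, 14 rose, 1 fell and 17 did not pass, and adjusted over the list alone 17 rose and 1 fell. The median log2 difference was 0.38, with 0.47 on slide 1 and 0.27 on slide 2 (camera adjusted p = 1.46e-07, 3.49e-07 with slide as a block, 5.71e-11 to 2.76e-05 over 24 alternatives; adjusted p = 0.464 with an estimated correlation). Besides Plin4, Sult1a1 and Mfsd2a, Fkbp5, a co-chaperone of the glucocorticoid receptor, rose 1.78-fold (95% confidence interval 1.46 to 2.18) and the metallothionein Mt1 1.36-fold, although another probe of Mt1 did not pass (adjusted p = 0.175). The member that fell was Per1, a clock gene, by 0.34 on the log2 scale. Sgk1 and Tsc22d3, 2 other members, gave 0.24 and 0.15 with adjusted p of 0.358 and 0.324.

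PPAR-alpha targets and genes of fatty acid oxidation were also higher. Of 33 measured, 12 rose and 0 fell, and 13 rose adjusted over the list alone. The median log2 difference was 0.11, with 0.08 on slide 1 and 0.14 on slide 2 (camera adjusted p = 0.000101, 0.000138 with slide as a block, 1.11e-05 to 0.00181 over 24 alternatives; adjusted p = 0.464 with an estimated correlation). The list's median deviation on fasted replicate 3, 0.13, stood apart from a mean of 0.02 on the other fasted arrays, and without that array the median log2 difference was 0.09. Next to Angptl4, Ehhadh, a peroxisomal enzyme, rose by a log2 difference of 0.43, and Cpt1a, which brings fatty acids into mitochondria, 1.19-fold (adjusted p = 0.036). Cpt1a did not pass with the replicate block (adjusted p = 0.0663; 0.0158 to 0.301 over its alternatives). Cpt2 gave 0.39 on its brightest probe and -0.49 on another, both past the threshold, so its direction is unsettled, and without it 11 genes of the list rose. Pdk4 gave 0.21 with an adjusted p of 0.0998. Oxidative phosphorylation genes had a median of 0.04, with 3 of 41 rising (camera adjusted p = 0.0277, 0.019 with slide as a block, 0.00345 to 0.128 over 24 alternatives; adjusted p = 0.706 with an estimated correlation). Adjusted over the list alone 0 rose, the median was 0.05 on slide 1 and 0.05 on slide 2, and the list missed the threshold under 10 of the 24 alternatives. The 3 genes that rose, Ndufb5, Atp5a1 and Uqcrc2, did not pass with the replicate block (adjusted p = 0.0744, 0.0789 and 0.0743).

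Genes of cholesterol biosynthesis were lower in fasted brain. Of 25 measured members, 16 fell and 0 rose, and 21 fell adjusted over the list alone. The median log2 difference was -0.24, with -0.26 on slide 1 and -0.20 on slide 2 (camera adjusted p = 2.7e-08, 6.53e-08 with slide as a block, 2.59e-10 to 1.26e-05 over 24 alternatives; adjusted p = 0.464 with an estimated correlation). Cyp51, the sterol demethylase, was 1.47-fold lower (95% confidence interval 1.32 to 1.63), Mvd, which makes isopentenyl diphosphate, 1.43-fold lower, and Hmgcs1, the cytosolic HMG-CoA synthase, 1.35-fold lower (adjusted p = 0.0029). Fatty acid synthesis and SREBP1 targets gave a median of -0.04 (camera adjusted p = 0.776), with 3 of 21 members rising and 2 falling, also adjusted over the list alone. Of these, Elovl6, a fatty acid elongase, fell by 0.36, while Acacb, which makes malonyl-CoA at mitochondria, rose by 0.46 on the log2 scale.

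Chaperone genes were lower. Of 17 measured heat shock genes, 10 fell and 0 rose, and 12 fell adjusted over the list alone. Their median log2 difference was -0.18, with -0.22 on slide 1 and -0.14 on slide 2 (camera adjusted p = 3.01e-05, 5.61e-05 with slide as a block, 3.54e-06 to 0.000154 over 24 alternatives; adjusted p = 0.464 with an estimated correlation). Chordc1, a partner of HSP90, was 1.43-fold lower (95% confidence interval 1.33 to 1.54; adjusted p = 0.00112), and Hsph1 and Stip1 fell by 0.32 and 0.28 on the log2 scale. Of 18 chaperones of the endoplasmic reticulum, 10 fell and 0 rose, and 11 fell adjusted over the list alone. Their median was -0.23, with -0.22 on slide 1 and -0.22 on slide 2 (camera adjusted p = 0.000132, 0.00015 with slide as a block, 6.35e-06 to 0.00101 over 24 alternatives; adjusted p = 0.464 with an estimated correlation). Sdf2l1 was 1.69-fold lower (95% confidence interval 1.51 to 1.89), and Creld2 and Calr fell by 0.47 and 0.38 on the log2 scale. In the other direction, Cirbp and Rbm3, RNA-binding proteins that rise in cooled cells, were 1.79-fold and 1.75-fold higher (adjusted p = 0.000792 and 0.00154). Another probe of Cirbp gave a log2 difference of 0.40, against 0.84 on its brightest probe. For Rbm3 another probe gave 0.86 and a further probe -0.23, the last with an adjusted p of 0.201. Together with Srsf5, which gave -0.09, they form a list of 3 genes with a camera adjusted p of 0.0662 and a fry adjusted p of 0.00276.

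Activity-regulated immediate early genes were lower. Of 25 measured, 11 fell and 1 rose, and adjusted over the list alone 12 fell and 1 rose. The median log2 difference was -0.24, with -0.29 on slide 1 and -0.24 on slide 2 (camera adjusted p = 0.000475, 0.00015 with slide as a block, 3.51e-05 to 0.0015 over 24 alternatives; adjusted p = 0.586 with an estimated correlation). Besides Egr2, Fosb was 1.76-fold lower (95% confidence interval 1.53 to 2.02) and Arc, which acts at synapses, 1.52-fold lower (95% confidence interval 1.25 to 1.84). Fos gave -0.46 with an adjusted p of 0.0547, and passed with slide as a block (adjusted p = 0.0367; 0.0367 to 0.262 over its alternatives). The member that rose was Btg2, an antiproliferative gene, by 0.70 on the log2 scale, named here after its value was seen. Clock genes did not pass as a list (median 0.00; camera adjusted p = 0.947): of 21 measured, 3 rose and 6 fell (4 and 6 adjusted over the list alone), among them Per2, by 0.47, and Dbp, by 0.33 on the log2 scale.

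**Figure D2:**
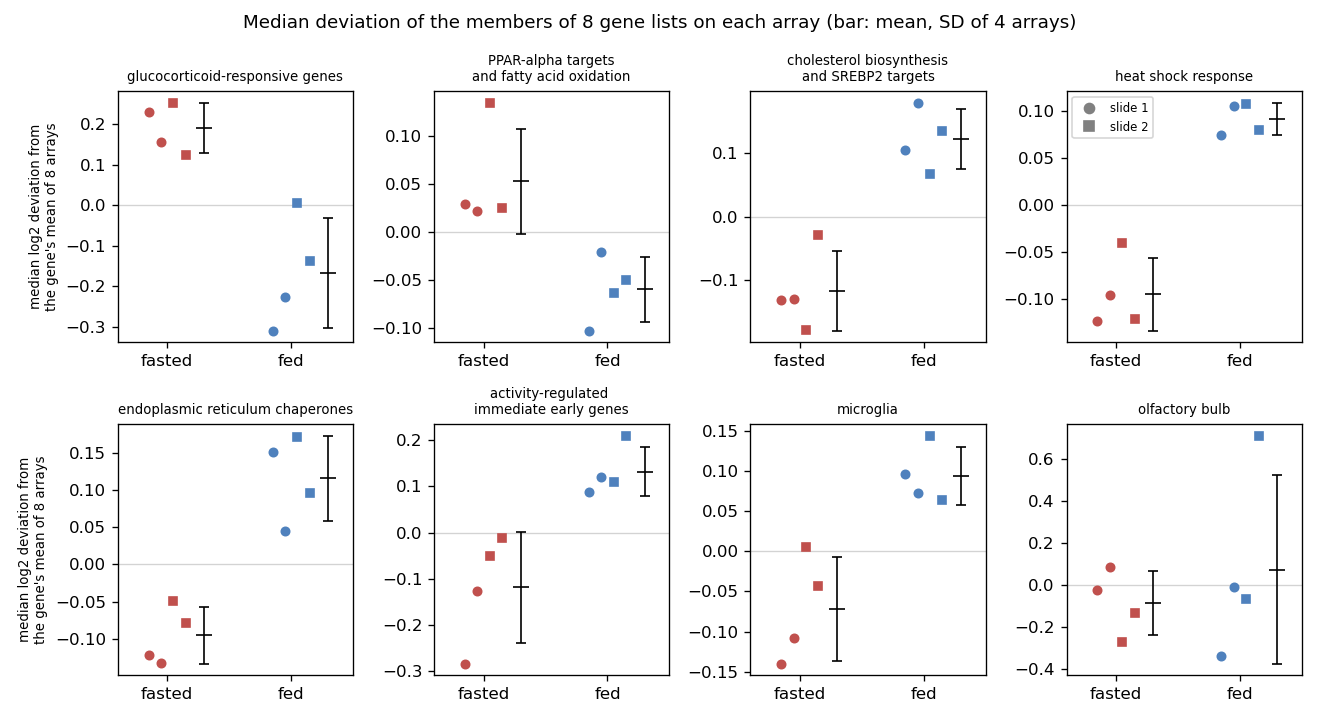
Median log2 deviation of the members of 8 gene lists from each gene's mean over 8 arrays, on each of the 4 fasted and 4 fed arrays. Circles are arrays of slide 1, squares arrays of slide 2, and bars give the mean and SD of 4 arrays; the olfactory bulb list reached 0.71 on fed replicate 4 and lay between -0.34 and 0.09 on the other arrays.

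Further pathway lists did not pass camera with the preset correlation, which gave the adjusted p of each list below. Of these lists, fry called FOXO targets (adjusted p = 0.00402) and the ATF4 list (0.0329). FOXO targets and insulin signalling genes had a median of 0.10 (adjusted p = 0.0662), with 7 of 21 members rising, among them Fbxo32, a ubiquitin ligase, by a log2 difference of 0.36, and 1 falling, Gadd45a, by 0.28. ATF4 and amino acid response genes had a median of 0.10 (adjusted p = 0.106), with 6 of 27 rising and 3 falling: Chac1 gave 0.36 and Psat1 0.33, against -0.54 for the cystine transporter Slc7a11. Interferon and inflammatory genes had a median of -0.38 (adjusted p = 0.0687), with 6 of 16 falling and 1 rising. Oas1a and Ifit3, both interferon-induced, fell by 0.61 and 0.63 on the log2 scale. Autophagy and lysosome genes had a median of 0.04 (adjusted p = 0.182; 3 of 28 rose), thyroid hormone responsive genes 0.07 (adjusted p = 0.371; 3 of 15 rose), ketone body metabolism 0.04 (adjusted p = 0.776; 2 of 12 rose and 1 fell) and glycolysis and glucose transport 0.00 (adjusted p = 0.947; 2 of 20 rose). Adjusted over the list alone, 7 rose and 1 fell for FOXO targets, 7 and 3 for the ATF4 list, 2 and 7 for interferon, 3 and 0 for autophagy, 3 and 0 for thyroid hormone, 4 and 3 for ketone bodies and 1 and 0 for glycolysis. In the last of these, the glucose transporter Slc2a1 rose by a log2 difference of 0.28.

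Among lists of cell type markers, only that of microglia passed camera with the preset correlation. Fry called microglia (adjusted p = 0.00654) and also astrocytes (0.00402), oligodendrocytes (0.005), oligodendrocyte precursors (0.0122) and neurons (0.0195). Of 13 microglia markers, 5 fell and 0 rose, also adjusted over the list alone. Their median was -0.14, with -0.20 on slide 1 and -0.11 on slide 2 (camera adjusted p = 0.00423, 0.0015 with slide as a block, 0.000101 to 0.0158 over 24 alternatives; adjusted p = 0.464 with an estimated correlation). Tmem119 fell by 0.42, Aif1 by 0.54 and P2ry12 by 0.43 on the log2 scale. Oligodendrocyte markers had a median of -0.12 (adjusted p = 0.0662; 5 of 12 fell and 1 rose), and Opalin, a myelin protein, fell by 0.79 on the log2 scale. Astrocyte markers had a median of 0.08 (adjusted p = 0.0687). Of 12, 3 rose, among them Fgfr3 by a log2 difference of 0.56, and 1 fell, the water channel Aqp4, by 0.41. Endothelial markers went both ways, with 3 of 14 rising and 3 falling (median -0.05; adjusted p = 0.871): Slco1a4 gave 0.50 and Tek -0.58. Adjusted over the list alone, 2 rose and 6 fell for oligodendrocytes, 4 and 1 for astrocytes and 4 and 3 for endothelial cells. The median was 0.07 for neurons (adjusted p = 0.172), 0.03 for oligodendrocyte precursors (0.58), -0.02 for mural cells (0.6), -0.13 for ependyma (0.352), -0.04 for meninges (0.436), 0.04 for choroid plexus (0.776) and -0.01 for blood cells (0.871), with the adjusted p in parentheses. Ttr, the main choroid plexus transcript, gave -0.05 (adjusted p = 0.592).

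Lists of brain region markers did not pass. The median was 0.07 for cortex and hippocampus (adjusted p = 0.352), 0.00 for the hypothalamus (0.776), -0.04 for the striatum (0.776), 0.08 for the thalamus (0.457), 0.01 for the cerebellum (0.969) and 0.14 for brainstem and monoaminergic nuclei (0.457). The olfactory bulb list had a median of -0.33 (adjusted p = 0.6), with 0.27 on slide 1 and -0.94 on slide 2. Its deviation on fed replicate 4 was 0.71, and 7 of its 9 genes were highest there. Without fed replicate 4, 2086 genes passed in the comparison of fasted with fed brain. Xist was well above background on the 8 arrays, with a log2 difference of -0.10 (adjusted p = 0.538). Of the sex markers 2 were kept and of the pituitary markers 1, too few for a test of these lists. The sex markers that were not kept were the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty. The sex of the mice was not tested. The median and the direction of the camera test differed in sign for the endothelial, hypothalamus, cerebellum and glycolysis lists, and the mean and the test did for the blood cell list.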

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

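Tests of array position, of the slides taken alone, of a general distortion of fed replicate 4, of endothelial markers and of single glucocorticoid-responsive genes under other fits were chosen after the results were seen. A sample was marked as far from the others of its group when its gap to the nearest, as a ratio to the group's range, exceeded Dixon's 95% critical value for 4 samples. This held in 22 of 414 groups of 4 values, and chance marks about 1 in 20, so the number itself does not stand out.

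The number of genes that differed between fasted and fed brain was set against other splits of the samples. Of the 8 splits that part all 4 same-numbered pairs, 1 gave as many genes and 1 as many probes, the real one, with 2797 and 4417, and the highest of the others gave 0; so few splits cannot give a share under 0.05. The other splits of all 35 keep pairs together, and the highest of them, which follows the slides, gave 43 genes and 94 probes. A difference carried by a single slide is argued against. Of 1168 genes with an unadjusted p under 0.01 on slide 1 alone, 97.9% had the same direction on slide 2. Over all genes tested the share with the same direction on both slides was 78.5%. A linear gradient along the slide as the whole cause is argued against too, since 63.7% of the genes remained past the threshold in the same direction with slide and position in the fit. The alternating positions stay open, because 0 fasted arrays sat at positions 2 or 4 and position parity cannot be told apart from fasting.

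The number of gene lists was set against the same splits. Of the 8 splits that part all pairs, 2 gave at least as many lists as the 8 of the real split, and the highest other gave 10. So few splits cannot give a share under 0.05. That other split exchanged only fasted replicate 4 and fed replicate 4. Over all 35 splits the highest other gave 12, with fasted replicate 4 and fed replicate 1 exchanged. Such splits still hold part of the fasting contrast, so they are no clean reference, also for the single lists below. The estimated correlation between members was 0.334 for the glucocorticoid list, against the preset 0.01. Taken singly over the 35 splits, the heat shock list had its smallest p in the real split, while p as small as the real one, that split included, was seen in 2 splits for cholesterol biosynthesis, PPAR-alpha targets and endoplasmic reticulum chaperones, in 5 for glucocorticoid-responsive genes and microglia, in 6 for immediate early genes and in 9 for oxidative phosphorylation.

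Olfactory bulb markers were highest in fed replicate 4, with a median deviation of 0.71. Trh in the fed group was marked there (ratio 0.863), at 1.43 against a mean of 0.67 in the others. More olfactory bulb tissue in that sample is a candidate explanation: 80% of 15 measured genes of a separate marker list, written before its values were seen, were highest there, where 1 array in 8 is the chance share. Of the 9 measured genes of the fixed olfactory bulb list, Trh also stands in the hypothalamus list and Th in the brainstem list. A distortion of that array that moves all region lists alike is argued against, as its largest absolute deviation over other region lists was 0.16. Over pathway and cell type lists its deviation reached -0.23, for blood cells. That array also had the fewest probes well above background, 24567, so a smaller distortion stays open. The labels name brain only, and no biological explanation was tested.

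Of 32 glucocorticoid-responsive genes, 14 rose and 1 fell in fasted brain, with a median log2 difference of 0.38 (adjusted p = 0.464 with an estimated correlation in limma camera). Different olfactory bulb content of the brains as the whole cause is argued against. The olfactory bulb median was 0.27 on slide 1 and -0.94 on slide 2, while that of the glucocorticoid list was 0.47 and 0.27. With the marker score in the fit the same 14 genes rose and the median was 0.40 (limma camera adjusted p = 3.54e-07, with the preset correlation). That score averaged -0.09 ± 0.15 on fasted and 0.07 ± 0.45 on fed arrays (SD), so this fit could change little. A linear gradient of array position as the whole cause is argued against too. With slide and position in the fit 11 of the 14 still rose, with a median of 0.33. A higher share of blood vessel cells as the whole cause is argued against. Median deviations of endothelial markers averaged 0.02 ± 0.05 on fasted and 0.01 ± 0.04 on fed arrays (SD, n = 4 each). Those of the glucocorticoid list averaged 0.19 ± 0.06 and -0.17 ± 0.14. The endothelial median log2 difference was -0.05, with an upper 95% bootstrap limit of 0.20, below 0.38. That limit resamples the 14 markers and not the arrays. Of these markers 3 rose (Slco1a4, 0.50, Abcb1a, 0.27, and Slc2a1, 0.28) and 3 fell (Cdh5, -0.26, Tek, -0.58, and Itm2a, -0.25). Under a stricter limit the test could not tell, so a smaller part of vessel cells in the rise stays open. A response to fasting, such as higher circulating corticosterone, may account for the pattern and was not tested, and alternating array position also stays open.

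Other samples far from their group are given as values. Fasted replicate 3 was highest for Angptl4 (ratio 0.917), Hk2 (0.917) and the list of PPAR-alpha targets (0.942), and lowest for Ifit3 (0.900). Fasted replicate 1 was highest for Isg15 (0.943) and lowest for the clock list (0.908) and the cortex and hippocampus list (0.840). Fasted replicate 2 was lowest for Prkcd (0.925), and fasted replicate 4 lowest for Bmp4 (0.893) and Kctd12 (0.894). Fed replicate 1 was lowest for Pla2g3 (0.873), Srsf5 (0.843) and Foxj1 (0.863) and highest for the oligodendrocyte list (0.844). Fed replicate 2 was highest for Acacb (0.833), Dbp (0.926) and the ATF4 list (0.943). Fed replicate 3 was highest for Hk2 (0.892). Fed replicate 4 was lowest for Pik3ip1 (0.859) and the neuron list (0.950) and highest for Tfe3 (0.874).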

How the results depend on the processing

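Slide with linear position, the olfactory bulb covariate and each slide alone were chosen after the data were seen. Gene and probe counts stayed within 1.5 times of 2797 and 4417 under the other scalings, variance models, array weights and slide as a block. Median scaling tipped the balance to rises, with 1270 genes higher and 905 lower, against 1426 and 1371, and 2014 probes higher and 1517 lower; the count of lower genes moved by over 1.5 times. The replicate block gave 2416 genes, 3957 probes and 8 lists, moved no count by over 1.5 times and changed no call of a list. Of 171 genes taken by the naming rule, 121 passed, of which 13 lost their call with the replicate block, and 7 others gained one. Leaving out an array gave 1764 to 2408 genes, 2782 to 3788 probes, 7 to 11 lists and a median log2 difference of -0.02 to -0.01; counts fell below the main one by over 1.5 times without fasted replicate 1, without fasted replicate 2 (2935 probes) and, for probes, without fed replicate 2 (2879), with fewer samples. Without a filter on dim probes 2605 probes and 1626 genes passed. More probes were then tested and entered the variance model, and the cause of the lower counts was not tested. An adjusted p under 0.1 gave 6637 probes, and a fold of at least 1.5 gave 237 probes and 152 genes. Each slide alone gave 0 probes and 0 genes, with 2 arrays per group, while 3475 and 2320 genes had an unadjusted p under 0.05. The median log2 difference of all kept probes was 0.00598 with median scaling, -0.0517 with no filter, -0.00115 with slide and position and -0.00132 on slide 2; the cause was not tested. With an estimated correlation 0 lists passed, and fry called 14. Of the 8 called lists, 7 passed with the preset correlation under 24 alternatives, and oxidative phosphorylation lost its call in 10 of these.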

Other observations

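The search of gene families was chosen after the data were seen. Lists that did not pass camera with the preset correlation held single genes that passed in limma. Among markers of oligodendrocyte precursors, Pdgfra, a growth factor receptor, rose by a log2 difference of 0.25 and Bmp4 by 0.33, while 0 of the 7 measured fell. Adjusted over the list alone, 2 rose and 1 fell, Gpr17, with a log2 difference of -0.17. Of 14 meningeal markers 3 fell and 0 rose, with Lum, a proteoglycan of the extracellular matrix, 1.35-fold lower. Adjusted over the list alone, 4 fell and 2 rose, among the latter Fmod with 0.23. Of the thyroid hormone responsive genes, Hr, a nuclear receptor corepressor, rose by a log2 difference of 0.34.

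Of 249 families of genes sharing a symbol stem with at least 8 measured members, 0 passed in limma's camera with the preset correlation, and 0 with an estimated correlation, while 26 had an unadjusted p under 0.05. The smallest adjusted p, 0.099, was shared by the Vmn and Olfr receptor families, the Klk peptidases and the Kcnk potassium channels, with median log2 differences of -0.16, -0.17, -0.35 and -0.16. Of their 38, 141, 13 and 11 measured genes, 4, 4, 2 and 5 fell, and 1 Olfr gene rose. The signal levels of these families were not examined. Without the filter on dim probes the median log2 difference of all probes was -0.0517, against -0.013 with it. A shift of dim probes in general was thus not separated from these family values.

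Of 17 heat shock genes 10 fell and 7 did not pass (adjusted p = 0.464 with an estimated correlation in limma camera), while Cirbp and Rbm3 rose, and a lower brain temperature in the fasted mice is a candidate explanation. A separate list of 16 heat-shock-inducible genes, written before its values were examined, had a median log2 difference of -0.0741 (camera p = 0.0115 with the preset correlation, 0.106 with an estimated one), and 3 of its genes fell and 0 rose. This goes in the predicted direction but is small, and the preset-correlation p has the weakness described for all lists. Temperature was not measured here, so lower neuronal activity or other effects of fasting stay open, as does alternating array position.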
